A study of Mus musculus with 4 samples.

How the data were processed

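Nuclei of the basolateral amygdala of WT and DISC1-N mice were profiled with 10x 3' v3 chemistry, per the labels' protocols, with 2 libraries per genotype. Bilateral tissue of 5 mice was pooled for each group and collected 6 h after tamoxifen, per the labels' protocols. The replicates of a genotype may share their mice, so the p-values may measure technical spread only. The deposited values are UMI counts per gene and barcode, made by the authors with Cell Ranger on mm10 and not normalized, per the file headers and the labels. The file headers give Cell Ranger 7.0.0 for both replicate 1 libraries and 6.0.2 for both replicate 2 libraries, while the submitters' processing notes name 7.0.0 for every library. Whether intronic reads were counted and how barcodes were called as nuclei are not given in the sources used here. Barcodes held at least 500 UMIs.

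The replicate number therefore stood for a processing batch that was balanced over genotype, and results are given without it and with it as a block. Libraries of the same number were closest: the mean chi-square per degree of freedom of a library pair was 8.87 for the replicate 1 libraries and 6.33 for the replicate 2 libraries, and 55.5 to 69.3 for all other pairs. The biological coefficient of variation in excitatory neurons was 0.175 without and 0.0564 with the block. The blocked fit has 1 residual degree of freedom.

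Nuclei with at least 500 genes and at most 5% mitochondrial UMIs were kept (26850 of 27313), and the nuclei of highest Scrublet score were removed at 0.8% per 1000 nuclei, which left 25332. Counts were clustered in scanpy 1.11.5 with leidenalg 0.10.2 (2000 variable genes, 30 principal components, 15 neighbours, resolution 0.5, seed 0). A cluster could be given a class only when at least 3 fixed markers of the class were detected, and 3388 nuclei were left without a class, in clusters of mixed markers, few markers, low depth with no marker of the class among the leading genes, or a median doublet score above 0.1; this score limit was set after the data were examined. A neuronal cluster of mixed transmitter type was split by clustering at resolution 1.0. Excitatory nuclei were clustered again without Wfs1, and the Wfs1-high subcluster was the one with at least 2 times the Wfs1 CPM of all excitatory nuclei.

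Counts were summed per class and library, and classes with at least 20 nuclei in each library were tested with edgeR 4.0.16 (quasi-likelihood, TMM factors, filterByExpr minimum count 10) in R 4.3.3, with a Benjamini-Hochberg adjusted p under 0.05 called. DESeq2 1.42.0 and limma 3.58.1 (voom) were run beside it. Class shares were compared with a two-sided exact permutation test of libraries and with edgeR on nuclei counts. Gene lists written before the data were examined were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over 124 list and class tests. Setting the called lists of classes other than excitatory neurons against 10000 random lists matched on gene length and level was chosen after the data were examined. Genes were matched to GENCODE vM21 by Ensembl ID (32158 of 32285), and coordinates are 1-based on mm10. Shares of nuclei with a UMI were repeated after thinning to 1000 UMIs per nucleus.

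Tests, lists, the Wfs1 rule and the rule for named genes were fixed before the data were examined. Named genes are, per class, the 10 largest rises and 10 largest falls in excitatory neurons, Wfs1-high neurons and astrocytes, and the 4 and 4 largest in other classes. They come from genes with an adjusted p under 0.05, a mean CPM of at least 20 and both DISC1-N libraries on the same side of both WT libraries, without gene models named Gm or Rik, mitochondrial, ribosomal protein and sex-linked genes. Where none passed, the 3 genes of lowest p are given as values. Disc1 in every class, Wfs1 and NMDA receptor subunits in excitatory neurons, 9 astrocyte genes and the 4 members of lowest p of each described list are always named, except that some genes are not reported here. Applying this rule to the blocked fit, with sides judged within replicate numbers, was chosen after the data were examined; other genes of the blocked fit that the report names, among them scarce genes and gene models, were also chosen after their values were seen.

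The tests were tried on simulated counts with 200 genes changed 1.5-fold or 2-fold. The fit without a block recovered 0% of them in every class. The blocked fit recovered more in every class but microglia, and made false calls, given beside each class, in all but microglia and endothelial cells. Alternatives were DESeq2 size factors, DESeq2, limma-voom, no expression filter, a mean CPM of at least 20, at least 1000 genes per nucleus, under 1% mitochondrial UMIs, a doubled share of doublets removed, classes by each nucleus's own marker score, sums thinned to equal depth, no nuclei above 3 times the class median depth, other Wfs1-high rules and leaving out each library. Differentiating oligodendrocytes and mural cells had too few nuclei for a test of genes.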

Results

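Single-nucleus RNA sequencing profiled the basolateral amygdala (BLA), a brain region that assigns threat and reward value to sensory cues, in wild-type (WT) mice and in DISC1-N mice. DISC1-N animals carry a modified form of Disc1, a scaffold protein gene linked to psychiatric illness. The series title concerns astrocytes, BLA neurons that express Wfs1 (an endoplasmic reticulum membrane protein gene) and risk assessment behaviour, so the comparison of the genotypes asks which cells and genes of the BLA differ. Each genotype had 2 libraries, replicate 1 and replicate 2, made from tissue collected 6 h after tamoxifen in both groups. The 4 libraries held 27313 barcodes. WT replicate 1 had 6124 barcodes and 48439711 UMIs, DISC1-N replicate 1 had 4654 and 40954622, WT replicate 2 had 8154 and 37840301, and DISC1-N replicate 2 had 8381 and 39643489. Median depth was 4037, 4780.5, 3282.5 and 3279 UMIs per barcode in the same order. After filtering and removal of 1518 putative doublets, 25332 nuclei remained.

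Neurons, glia and vascular cells were recovered from every library, and their shares were close in the 2 genotypes. Excitatory neurons made up 22.2% ± 2.87 (SD, n = 2) of WT nuclei and 23.9% ± 1.30 of DISC1-N nuclei, and inhibitory neurons 26.8% ± 5.82 and 25.6% ± 5.07. Astrocytes were 12.5% ± 2.81 and 11.6% ± 4.08, oligodendrocytes 9.64% ± 0.470 and 8.57% ± 1.31, oligodendrocyte precursors 7.71% ± 0.879 and 6.86% ± 1.01, and microglia 5.33% ± 0.637 and 5.47% ± 1.58. Endothelial cells were the only class whose DISC1-N libraries both lay above both WT libraries, at 0.700% ± 0.085 against 0.438% ± 0.0535, a difference of 0.360 percentage points in replicate 1 and 0.164 in replicate 2. The two-sided exact permutation p was 0.333 for this class, the smallest value that 2 against 2 libraries allow. edgeR's quasi-likelihood test on nuclei counts gave it an adjusted p of 0.643, and 0.325 with the replicate number as a block. No other class differed either (exact permutation p from 0.667 to 1 for the remaining classes; edgeR adjusted p = 0.906 for each). Differentiating oligodendrocytes (0.363% and 0.432%) and mural cells (0.512% and 0.565%) were rare. A further 14.5% ± 12.6 of WT and 16.3% ± 14.4 of DISC1-N nuclei stayed without a class. Their share was 23.4% and 26.5% in the replicate 1 libraries but 5.55% and 6.13% in the replicate 2 libraries. It thus differed more between replicate numbers than between genotypes. Among the nuclei without a class, 2115 formed 1 cluster that scored highest for excitatory neurons. It was left out for its median doublet score of 0.123, above the limit set after the data were examined. It held 950 WT and 846 DISC1-N nuclei of replicate 1, against 192 and 127 of replicate 2. Excitatory nuclei kept in replicate 1 numbered 1162 and 1000.

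**Figure D1:**
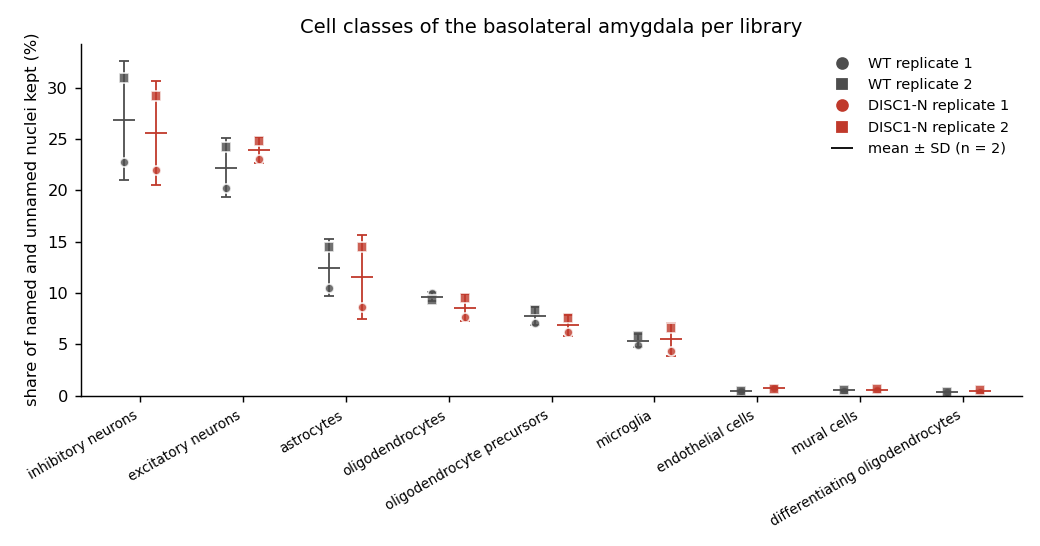
Share of kept nuclei (percent, vertical axis) in each cell class, with 1 point per library and a bar at the mean of each genotype (n = 2 libraries per genotype). Endothelial cells are the class in which both DISC1-N libraries lie above both WT libraries, at 0.700% against 0.438%.

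Disc1, the modified gene, was detected in both genotypes and was higher in both DISC1-N libraries than in both WT libraries of excitatory neurons. Its level there was 8.43 ± 0.151 CPM (UMI counts scaled to library size; SD, n = 2) in WT and 13.3 ± 1.71 in DISC1-N libraries, a log2 fold change of 0.65. In Wfs1-high excitatory neurons Disc1 stood at 8.20 ± 7.41 and 21.9 ± 6.44 CPM, and in astrocytes at 30.2 ± 10.5 and 37.0 ± 14.4. The levels were 8.28 ± 1.41 and 9.34 ± 1.36 CPM in inhibitory neurons, 57.4 ± 5.19 and 61.6 ± 13 in oligodendrocyte precursors, and 122.1 ± 0.526 and 104.0 ± 40.8 in microglia. None of these differences passed edgeR's test after Benjamini-Hochberg adjustment. With the replicate number as a block, the Disc1 estimate in excitatory neurons was 0.65 ± 0.15 (SE, adjusted p = 0.0871 in edgeR). A Disc1 UMI was seen in 6.47% of WT and 10.4% of DISC1-N excitatory nuclei (median depth 7451.5 and 8320 UMIs), against 0.391% and 0.943% of oligodendrocytes (1361 and 1343.5 UMIs), where the gene had too few UMIs for a test. After thinning to 1000 UMIs per nucleus, which left out 4 WT and 5 DISC1-N excitatory nuclei, the shares were 0.701% and 1.07%. Disc1 (mm10 chromosome 8, 125054195 to 125261858) overlaps an antisense gene model, Gm16237, and a 3' assay may not see the modified transcript, so these levels do not check the genotype labels.

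Excitatory neurons of DISC1-N mice had lower summed levels of mitochondrially encoded transcripts, and of Scg2 and Hspa5, in both replicate numbers. In replicate 1 the mitochondrial sum also fell from WT to DISC1-N in astrocytes (3574 to 2592 CPM) and oligodendrocytes (5754 to 4556). It fell likewise in precursors (4134 to 3129) and microglia (5221 to 4096). In replicate 2 these sums were 742 and 853, 1269 and 1266, 838 and 945, and 1303 and 1665 CPM in the same order. Scg2, which encodes the granin secretogranin II of dense-core vesicles, stood at 44.8 and 24.4 CPM in the WT libraries of replicates 1 and 2 and at 29.7 and 12.3 CPM in the DISC1-N ones. Hspa5, the main chaperone of the endoplasmic reticulum, stood at 77.7 and 46.5 CPM in WT and 58.4 and 29.8 in DISC1-N libraries. Nwd1, which encodes a protein with NACHT and WD40 domains, went the other way, from 15.6 and 20.2 CPM in WT to 29.7 and 33.4 CPM in DISC1-N libraries. Levels of most of these genes differed more between the replicate numbers than between the genotypes. Replicate numbers also differed in the software version in the file headers, so each comparison was made both across all 4 libraries and within replicate numbers (a block in the model).

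Across the 4 libraries without a block, edgeR called 0 of 16163 genes in excitatory neurons (124 at an unadjusted p under 0.05), as did DESeq2 (48) and limma-voom (111). With the replicate number as a block, edgeR called 8 genes higher and 33 lower in DISC1-N excitatory neurons. Applied to the blocked fit, the rule for named genes took 1 rise and 10 falls. Nwd1 (chromosome 8, 72646711 to 72717876) rose by a log2 fold change of 0.82 ± 0.11 (SE, adjusted p = 0.000751). Scg2 (chromosome 1, 79434669 to 79440120) fell by 0.77 ± 0.11 (adjusted p = 0.00233). The other falls in the blocked edgeR fit were Grp, the gene of gastrin-releasing peptide (log2 fold change -0.66 ± 0.12, adjusted p = 0.0103), and Timp2, an inhibitor of matrix metalloproteinases (-0.61 ± 0.09, 0.00206). Also lower were Arhgap6, a GTPase activating protein (-0.58 ± 0.10, 0.00897) and Eef1b2, a translation elongation factor (-0.58 ± 0.09, 0.00623). They also included Hspa5 (-0.52 ± 0.09, 0.00744), the progesterone receptor membrane component Pgrmc1 (-0.50 ± 0.08, 0.00439), the neuropeptide gene Sst (-0.50 ± 0.10, 0.0377), and the cytosolic chaperones Hsp90ab1 (-0.46 ± 0.07, 0.00429) and Hspa8 (-0.45 ± 0.08, 0.0251). Grp, Timp2, Arhgap6 and Eef1b2 overlap other gene models, so their counts are uncertain. With subclustering at resolution 1.0, Grp and Arhgap6 were leading genes of an excitatory subcluster of 68 nuclei. It held 17 WT and 5 DISC1-N nuclei of replicate 1, and 36 and 10 of replicate 2. Arhgap6 also led a subcluster with 102 and 120 nuclei in replicate 1 and 146 and 205 in replicate 2. Whether these 2 falls came from the numbers of such nuclei was not tested. Sst was a leading gene of an inhibitory neuron cluster, and Nwd1 was far higher in astrocytes than in excitatory neurons. Whether the counts of Sst and Nwd1 here came from other cells was not tested. The 3 genes of lowest p without a block were all scarce. Cartpt, a neuropeptide precursor gene, stood at 4.48 ± 0.741 CPM in WT and 1.00 ± 0.368 in DISC1-N libraries. Plut, a long non-coding RNA antisense to Pdx1, stood at 0.166 ± 0.0423 and 1.88 ± 0.566, and the model Gm15839 at 3.61 ± 0.391 and 10.0 ± 2.40. On simulated counts for excitatory neurons, the blocked fit recovered 52% of genes changed 1.5-fold and 77.8% of those changed 2-fold with 30 false calls among 16207 genes, and the fit without a block recovered 0% of either. Leaving out 1 library without a block gave 3 calls without WT replicate 1, 14 without DISC1-N replicate 1, 0 without WT replicate 2 and 13 without DISC1-N replicate 2.

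**Figure D2:**
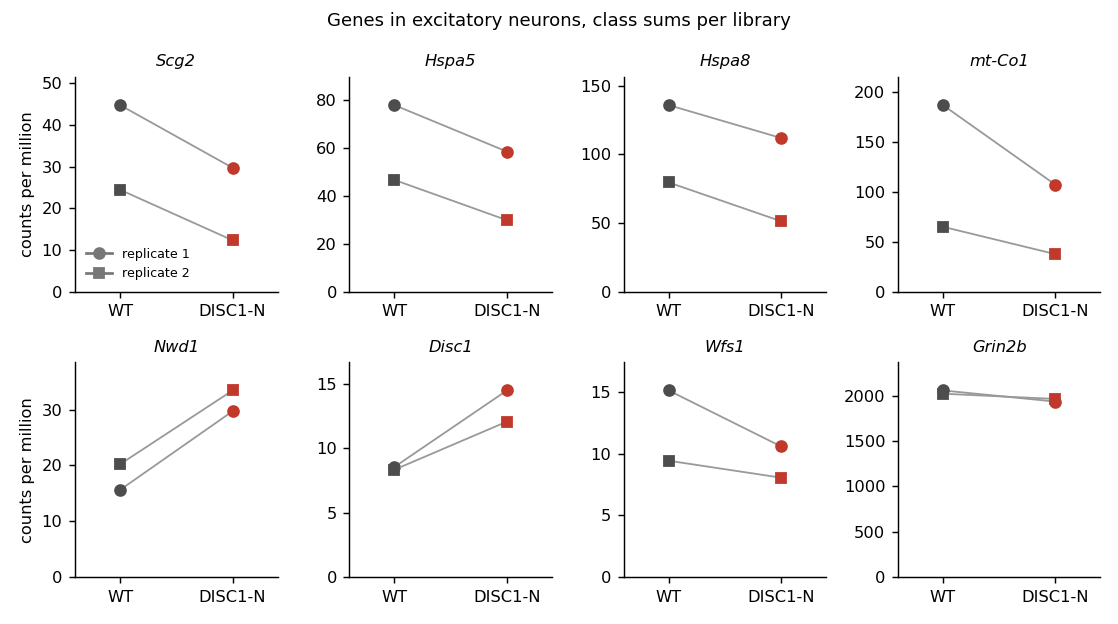
Level (CPM, vertical axis) of 8 genes in excitatory neurons, with 1 point per library and a line joining the WT and DISC1-N library of the same replicate number. The lines for Scg2, Hspa5, Hspa8 and mt-Co1 go down from WT to DISC1-N in both replicate numbers, those for Nwd1 and Disc1 go up, and Wfs1 and Grin2b passed no test.

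Among the lists fixed beforehand, 13 of 13 measured mitochondrially encoded genes had negative estimates in DISC1-N excitatory neurons. Their median log2 fold change was -0.93 in the blocked fit (camera in limma with a preset correlation of 0.01, adjusted p = 1.32e-113; -0.95 and 1.75e-12 without a block). Of these, 10 fell over all genes tested and 13 adjusted over the list alone. Lowest in p were mt-Nd2, a subunit of respiratory complex I (-1.26 ± 0.10), mt-Co3, a subunit of cytochrome c oxidase (-0.96 ± 0.08), mt-Nd4 (-0.93 ± 0.08) and mt-Cytb (-0.86 ± 0.08). The nuclear-encoded oxidative phosphorylation genes lay lower in the blocked fit, with 76 of 79 below 0, a median of -0.17 and a camera adjusted p of 3.01e-16. Of these, 0 passed over all genes and 11 adjusted over the list alone, with Ndufa4 (-0.38 ± 0.08), Cox8a (-0.30 ± 0.07), Ndufa5 and Ndufc2 lowest in p. Cytosolic ribosomal protein genes were shifted likewise (75 of 78 below 0, median -0.19, adjusted p = 6.19e-21). None passed over all genes (0) and 18 did adjusted over the list alone, with Rpl23 (-0.41 ± 0.09), Fau (-0.29 ± 0.08), Rpl15 and Rpl24 lowest in p. Of 22 measured genes of the unfolded protein response, 19 lay below 0 (median -0.20, adjusted p = 3.46e-09). Hspa5 and Hsp90b1 (-0.42 ± 0.07) fell over all genes, 7 passed adjusted over the list alone, and the lectin chaperones Calr and Canx were next in p. Heat shock genes had a median of -0.21 over 13 members (adjusted p = 9.41e-07), with 3 falls over all genes (Hspa8, Hsp90ab1 and Hsp90aa1, -0.38 ± 0.07) and 4 adjusted over the list alone. Without a block this list had an adjusted p of 0.0913. Immediate early and activity-induced genes had 23 of 25 members below 0 (median -0.20, adjusted p = 8.38e-06), 0 past the threshold over all genes and 2 adjusted over the list alone. Estimates were -0.82 ± 0.21 for Egr1 and -1.39 ± 0.36 for Fos, followed in p by Egr3 and Bdnf. With an estimated correlation none of these lists passed (adjusted p = 0.812 with the block and 0.915 without for each of the 6). In replicate 2, 17 WT nuclei (0.926%) with at least 1% mitochondrial UMIs held 35.9% of the mitochondrial UMIs of WT excitatory neurons, and without such nuclei the levels were 272 CPM in WT and 229 in DISC1-N. The median share of mitochondrial UMIs per nucleus was 0.118% in WT and 0.0642% in DISC1-N replicate 1, but 0.0170% and 0.0198% in replicate 2.

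Synaptic gene lists moved little. The NMDA receptor and postsynaptic density list had 22 of 25 members below 0 in the blocked fit but a median of only -0.06 (camera adjusted p = 0.0229, 0.172 without the block). It had 0 genes past the threshold over all genes, 1 adjusted over the list alone and an adjusted p of 0.812 with an estimated correlation. The NMDA receptor subunit genes Grin1 (-0.08 ± 0.08), Grin2a (-0.04 ± 0.06) and Grin2b (-0.06 ± 0.06) did not pass (edgeR blocked adjusted p from 0.922 to 0.957). Nrgn, a calmodulin-binding postsynaptic protein, had -0.26 ± 0.06, with the scaffold genes Dlg4 and Dlgap3 and the kinase Camk2b also low in p. Synaptic vesicle genes had a median of -0.01 (adjusted p = 0.00426, and 0.812 with an estimated correlation), with 1 gene lower over all genes and 5 adjusted over the list alone. The former was the vesicle glycoprotein Sv2c (-0.82 ± 0.16), and Syt4, Syt11 and Syp were next in p. Sodium channel and axon initial segment genes had a median of -0.04 (adjusted p = 0.042, and 0.812 with an estimated correlation), with 0 genes past the threshold over all genes and 1 adjusted over the list alone. The lowest p was that of Fgf13 (-0.33 ± 0.08), a sodium channel binding factor, ahead of Scn2a, Scn2b and Scn3b. Partners of the DISC1 protein (29 genes, median -0.02, adjusted p = 0.356) and schizophrenia exome genes (median -0.01, adjusted p = 0.584) were not called. Nor were AMPA, kainate and metabotropic glutamate receptors (median 0.00, camera adjusted p = 0.827), GABA receptors (-0.03, 0.0741), potassium and HCN channels (-0.04, 0.0715), calcium channels (0.02, 0.963) or monoamine and neuropeptide receptors (-0.08, 0.963). Markers of other classes were carried at low levels in excitatory neurons. Inhibitory markers summed to 340 and 292 CPM in the WT libraries of replicates 1 and 2 and to 272 and 245 in the DISC1-N ones. Oligodendrocyte markers summed to 101 and 60.0 against 85.2 and 54.1, and endothelial markers to 42.1 and 49.0 against 50.8 and 52.6.

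Wfs1 itself was low in excitatory neurons. Its level was lower in the DISC1-N library of both replicate numbers, but the difference passed no test. The fit without a block recovered 0% of simulated 2-fold changes, so it cannot tell a fall of this size from none. Wfs1 (chromosome 5, 36966104 to 36989205) stood at 12.3 ± 4.03 CPM in WT and 9.31 ± 1.79 in DISC1-N libraries (log2 fold change -0.39; -0.36 ± 0.15 with the block, edgeR adjusted p = 0.550), and the estimate was -0.07 without WT replicate 1. A Wfs1 UMI was found in 8.27% of WT and 7.40% of DISC1-N excitatory nuclei at median depths of 7451.5 and 8320 UMIs. It was found in 17.4% and 15.9% of inhibitory nuclei (3934 and 4191 UMIs), 3.89% and 3.30% of astrocytes (1847 and 1928 UMIs) and 2.74% and 2.36% of oligodendrocytes (1361 and 1343.5 UMIs). Thinned to 1000 UMIs, the shares were 1.44% and 0.828% in excitatory nuclei, 5.41% and 4.33% in inhibitory nuclei, 1.57% and 1.58% in astrocytes and 1.77% and 1.03% in oligodendrocytes. Thinning left out 4 WT and 5 DISC1-N excitatory nuclei, 12 and 51 inhibitory nuclei, 40 and 28 astrocytes and 203 and 183 oligodendrocytes.

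One excitatory subcluster of 278 nuclei (61 Wfs1 UMIs) was found without using Wfs1. Its Wfs1 level was at least 2 times that of all excitatory nuclei in the mean of the 4 libraries (26.3 against 10.95 CPM). The latter covers all nuclei clustered again, some of them later left without a class, which the next values leave out. Per library the levels were 28.8 against 15.1 CPM in WT replicate 1, 35.3 against 10.6 in DISC1-N replicate 1, 29.6 against 9.42 in WT replicate 2 and 11.6 against 8.04 in DISC1-N replicate 2, so WT replicate 1 and DISC1-N replicate 2 stayed below the rule taken alone. Its leading genes were Plpp3, Grik1, Col12a1, Glis3 and Sema5a. It made up 4.67% ± 0.448 (SD, n = 2) of WT and 4.60% ± 0.991 of DISC1-N excitatory nuclei (two-sided exact permutation p = 1). With a rule of 1.5 times the share was 16.5% ± 2.13 in WT and 13.3% ± 1.83 in DISC1-N, and with subclustering at resolution 1.0 it was 8.48% ± 0.667 and 6.65% ± 0.917. Under both of these rules the share was lower in the DISC1-N library of each replicate number (exact permutation p = 0.333 for each). In these Wfs1-high neurons edgeR called 0 of 7627 genes without a block (125 at an unadjusted p under 0.05; DESeq2 0 and 13, limma-voom 0 and 132), and 3 higher and 5 lower with it. Dach2, a transcriptional regulator on the X chromosome, rose by a log2 fold change of 1.58 ± 0.36 in the blocked fit (17.3 and 16.3 CPM in WT, 66.2 and 38.2 in DISC1-N libraries; adjusted p = 0.0140). Rab11b, a GTPase of recycling endosomes, fell by 2.10 ± 0.47 (40.3 and 32.6 CPM against 2.21 and 11.6, blocked edgeR adjusted p = 0.0112). DISC1-N replicate 1 had 453413 UMIs over 39 nuclei here, so its Rab11b level lay at the floor of the counts. The gene model AC149090.1, on an unplaced sequence, also fell (-0.88 ± 0.13), and these 3 calls held under 4, 4 and 5 of 10 alternatives (0 genes called in DESeq2, with a doubled doublet share, by own marker score or thinned). Gpr155 stood at 77.6 ± 1.17 and 138.6 ± 19.2 CPM (blocked adjusted p = 0.0626). Mitochondrially encoded genes had 10 of 10 members below 0 (median -0.89, camera adjusted p = 1.48e-17), 3 of which fell over all genes and 7 adjusted over the list alone. In WT replicate 2, 1 of 80 nuclei held 33.8% of the mitochondrial UMIs, and without it the replicate 2 levels were 260 CPM in WT and 230 in DISC1-N, with a median share per nucleus of 0.0144% and 0.0206%. Oxidative phosphorylation (median -0.23), ribosomal protein (-0.26), unfolded protein response (-0.17), heat shock (-0.14) and NMDA receptor and postsynaptic density (-0.08) genes were lower too, with camera adjusted p from 9.32e-05 to 0.0338. These 5 lists had 0 genes past the threshold over all genes and 1, 2, 0, 2 and 0 adjusted over the list alone. With an estimated correlation the adjusted p was 0.812 for all 6 lists, and against random lists matched on gene length and level heat shock lay at percentile 25.2 and the unfolded protein response at 6.50. The members of lowest p were mt-Co3, mt-Atp6, mt-Nd4 and mt-Nd2; Ndufb3, Sdhc, Ndufa4 and Ndufa13; Rpl4, Rpl37, Rpl30 and Rpl3; Hspa5, Hsp90b1, Syvn1 and Xbp1; Hspa8, Hsp90aa1, Hsp90ab1 and Dnaja1; and Nrgn, Dlg4, Shank2 and Homer2. Wfs1 in this subcluster stood at 29.2 ± 0.570 and 23.4 ± 16.8 CPM, and Grin1, Grin2a and Grin2b had log2 fold changes of 0.00, -0.05 and -0.08. On simulated data for Wfs1-high neurons the blocked fit recovered 11.8% of genes changed 1.5-fold and 53.9% of those changed 2-fold, with 4 false calls. Without WT replicate 1, DISC1-N replicate 1, WT replicate 2 or DISC1-N replicate 2, the count without a block was 3, 5, 9 and 0.

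Inhibitory neurons shared much of the excitatory pattern. Summed mitochondrially encoded transcripts stood at 2439 and 712 CPM in the WT libraries of replicates 1 and 2 and at 1566 and 506 in the DISC1-N ones. In WT replicate 2, 20 nuclei (0.853%) carried 24.2% of these UMIs; without such nuclei the replicate 2 levels were 546 and 506 CPM, and the median share per nucleus was 0.0386% in WT and 0.0416% in DISC1-N. The extracellular matrix glycoprotein gene Reln stood at 71.1 and 97.6 CPM in WT and 103.5 and 115.2 CPM in DISC1-N libraries. Of 15300 genes, edgeR called 0 without a block (83 at an unadjusted p under 0.05; DESeq2 0 and 20, limma-voom 0 and 81) and 16 higher and 46 lower with it. The blocked calls numbered 0 in DESeq2, 92 in limma-voom, 3 with a doubled doublet share, 9 with under 1% mitochondrial UMIs and 12 thinned, and the genes named next were each called under 4 to 7 of 10 alternatives. The rises in the blocked fit included Stk31, a kinase gene (log2 fold change 0.59 ± 0.10, adjusted p = 0.000405), and Reln (0.38 ± 0.09, 0.0203). They also held the small nucleolar RNA host genes Snhg9 (0.56 ± 0.11, 0.00180), whose model overlaps Rps2, and Snhg20 (0.43 ± 0.08, 0.00893). Reln and Stk31 were leading genes of separate neuronal clusters, and whether their rises came from the shares of such nuclei was not tested. The falls included Psmb5, a catalytic proteasome subunit (-0.63 ± 0.12, 0.00160), Ptgds, the prostaglandin D2 synthase that oligodendrocytes also express (-0.63 ± 0.10, 0.000135), Tac1, the substance P precursor gene (-0.57 ± 0.11, 0.00449), and Cct2, a chaperonin subunit (-0.54 ± 0.12, 0.0232). Without a block the 3 genes of lowest p were Vmn1r90 (0.453 ± 0.217 CPM in WT and 2.90 ± 1.62 in DISC1-N), AC149090.1 (646.3 ± 78.9 and 331.1 ± 117) and B930036N10Rik (1.88 ± 0.338 and 0.446 ± 0.0587). Leaving out WT replicate 1, DISC1-N replicate 1, WT replicate 2 or DISC1-N replicate 2 gave 1, 9, 2 and 3 calls.

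In inhibitory neurons 13 of 13 mitochondrially encoded genes (median -0.54, camera adjusted p = 1.96e-46; 11 fell over all genes and 11 adjusted over the list alone) lay below 0 in the blocked fit. So did 12 of 12 heat shock genes (median -0.29, adjusted p = 1.17e-11; 3 and 8). Oxidative phosphorylation genes had a median of -0.18 (1 past the threshold over all genes and 11 adjusted over the list alone) and ribosomal protein genes -0.17 (2 and 18). The unfolded protein response list had -0.24 (adjusted p = 6.38e-07; 0 and 6). The activity-induced list had -0.20 (adjusted p = 1.28e-06; 1, the neurosecretory precursor gene Vgf at -0.35 ± 0.09, and 5). The vesicle list had -0.03 (adjusted p = 0.0301; 1, the synaptotagmin Syt11 at -0.35 ± 0.08, and 1). With an estimated correlation the adjusted p was 0.812 for each of these 7 lists, and the vesicle list lay at percentile 8.85 of random lists matched on gene length and level. The members of lowest p were mt-Nd2, mt-Co2, mt-Co3 and mt-Nd4; Hspa8, Hsp90aa1, Hsp90ab1 and Hspd1; Cox6a2, Cox7a2, Uqcr11 and Atp5h; Rpl7, Rpl23 and Rpl37; Hsp90b1, Calr, Canx and Pdia4; Vgf, Junb, Egr1 and Arc; and Syt11, Syt4, Sv2b and Syp. Of the genes called lower in excitatory and inhibitory neurons (33 and 46 among 14844 tested in both), 18 were shared against 0.102 for independent lists, among them 10 mitochondrially encoded genes, Cartpt, Gapdh, Hsp90aa1, Hsp90ab1, Hspa8, Pgrmc1 and Serinc1. Both lists come from the same 4 libraries, so 0.102 is not the overlap expected without a genotype effect. The excess may come from the shared libraries and cannot measure a shared genotype effect. Excitatory markers in these nuclei summed to 565 and 402 CPM in the WT libraries and 505 and 376 in the DISC1-N ones, and oligodendrocyte markers to 128 and 73.0 against 100.2 and 60.7. With simulated inhibitory counts, the blocked fit recovered 54.6% of genes changed 1.5-fold and 80.6% of those changed 2-fold, with 20 false calls.

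Astrocytes, the other cell type in the series title, kept their uptake and coupling genes at similar levels. Slc1a2, the main glutamate transporter, stood at 5804 ± 1379 CPM (SD, n = 2) in WT and 5684 ± 1337 in DISC1-N libraries, and the transporter Slc1a3 at 2715 ± 558 and 2834 ± 487. The connexin Gja1 stood at 477 ± 206 and 440 ± 99.0, and the water channel Aqp4 at 130.8 ± 0.475 and 125.6 ± 10.0. Glul, the glutamine synthetase gene, had a log2 fold change of 0.26 ± 0.11 in the blocked fit, Gfap, the intermediate filament raised in reactive astrocytes, 0.46 ± 0.23, and Kcnj10, a potassium channel, -0.13 ± 0.26. For D-serine synthesis, Srr (serine racemase) stood at 64.6 ± 0.290 and 75.8 ± 4.44 CPM and Phgdh, the first enzyme of serine synthesis, at 52.7 ± 7.67 and 49.0 ± 11.7. None of these 9 genes passed (blocked edgeR adjusted p of at least 0.551).

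Camera at the preset correlation called 2 fixed lists higher in astrocytes, glucocorticoid response and circadian clock genes. Glucocorticoid response genes had 12 of 16 members above 0 and a median of 0.11 in the blocked fit (camera adjusted p = 0.000501; 0.15 and 0.00605 without the block), with 0 past the threshold over all genes and 2 adjusted over the list alone. Examples are the immunophilin Fkbp5 (0.33 ± 0.12), the NF-kappa-B inhibitor Nfkbia (0.68 ± 0.20), Errfi1, a feedback inhibitor of the EGF receptor (0.82 ± 0.32), and the metallothionein Mt1. Circadian clock genes had 13 of 18 members above 0 and a median of 0.12 (adjusted p = 0.00714; 0.037 without the block) with 0 genes past either threshold, with Per2 (0.46 ± 0.20), Nr1d2 (0.43 ± 0.16), Hlf and Ciart lowest in p. Lower lists were oxidative phosphorylation (median -0.20, adjusted p = 1.17e-11; 0 over all genes and 10 adjusted over the list alone), ribosomal proteins (-0.17, 1.17e-11; 0 and 2), and heat shock (-0.20, 0.000295; 1 and 3). Also lower were activity-induced genes (-0.26, 0.00718; 0 and 3) and the unfolded protein response (-0.17, 0.0431; 0 and 0). The unfolded protein response list had a median log2 ratio of 0.06 in replicate 1 and -0.21 in replicate 2. All 7 list calls were lost in camera with an estimated correlation (adjusted p = 0.812). Against random lists matched on gene length and level, ribosomal protein genes of astrocytes lay at percentile 6.51, heat shock at 3.29 and glucocorticoid response at 97.53, the last with median log2 ratios of 0.27 in replicate 1 and 0.03 in replicate 2. Lowest in p were Ndufa8, Ndufs5, Atp5h and Ndufa6; Rpl23, Rpl27 and Rpl15; Hspa8, Hsp90aa1, Hsp90ab1 and Dnajb1; Junb, Egr3, Bdnf and Vgf; and Hspa5, Calr, Pdia4 and Dnajb11. By fry, only heat shock in the blocked fit passed among all lists and classes (adjusted p = 0.00258), and fry does not compare a list with other genes. Lists of D-serine and glycine metabolism (median -0.04, adjusted p = 0.963), astrocytic homeostasis (0.01, 0.275), coupling and calcium signalling (-0.10, 0.107), reactive astrocyte genes (0.14, 0.236), secreted synapse organisers (0.01, 0.958) and DISC1 partners (-0.03, 0.958) were not called.

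Of 11780 genes in astrocytes, edgeR called 0 without a block (77 at an unadjusted p under 0.05; DESeq2 0 and 11, limma-voom 0 and 67) and 7 higher and 10 lower with it. The blocked calls numbered 0 in DESeq2, 12 in limma-voom, 0 with under 1% mitochondrial UMIs, 0 thinned and 1 without nuclei above 3 times the class median depth. The nuclear RNA Malat1 rose by 0.14 ± 0.03 (adjusted p = 0.00493). The named falls were Cct5, a chaperonin subunit (-0.89 ± 0.22), Eef1b2 (-0.73 ± 0.17), Sst (-0.59 ± 0.15), Bex2 (-0.54 ± 0.14), Hspa8 (-0.51 ± 0.12) and Rtn1, a reticulon of neurons (-0.47 ± 0.12), with adjusted p from 0.041 to 0.0488, each called under 2 or 3 of 10 alternatives. Sst, Bex2 and Rtn1 are neuronal genes, and excitatory markers summed to 442 and 169 CPM in the WT astrocyte libraries and 377 and 149 in the DISC1-N ones. The genes of lowest p without a block were the model Gm4710 (35.5 ± 6.40 and 11.9 ± 3.05 CPM), Pkp1, a desmosome protein gene (0.953 ± 1.35 and 13.1 ± 4.86), and the vesicular GABA transporter Slc32a1 (18.8 ± 5.69 and 5.81 ± 2.60). For simulated astrocyte counts the blocked fit recovered 23.7% of genes changed 1.5-fold and 57.9% of those changed 2-fold, with 5 false calls.

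**Figure D3:**
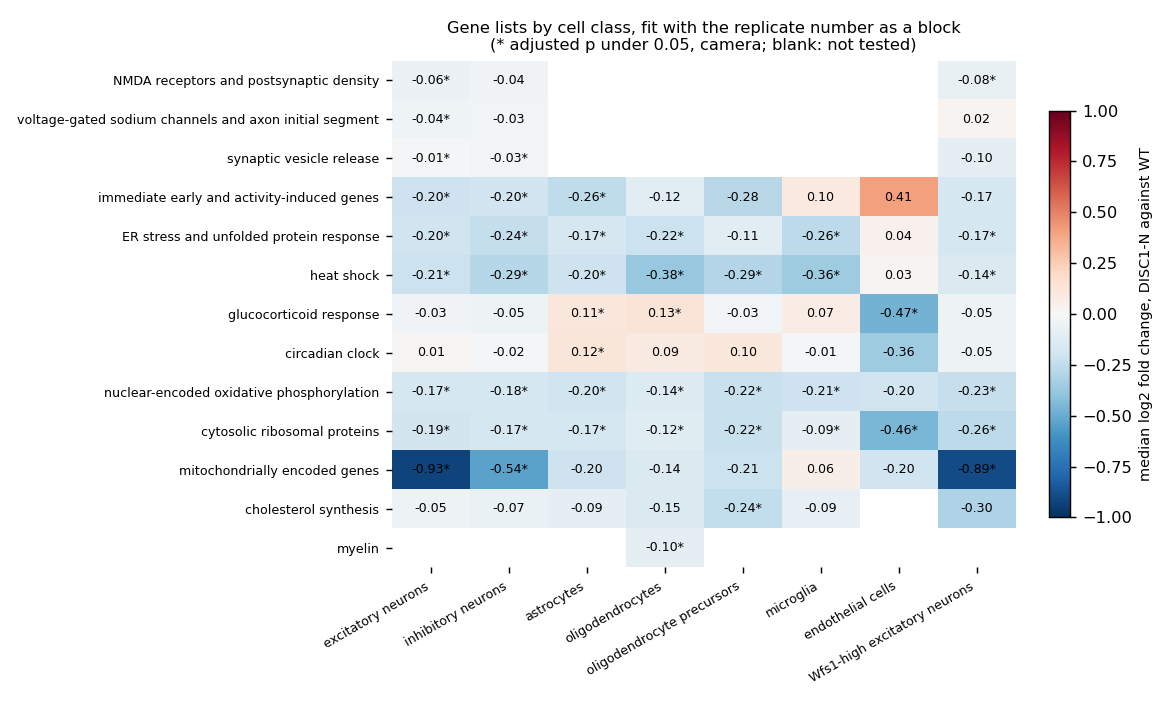
Median log2 fold change (DISC1-N against WT, blocked edgeR fit, colour scale) of 13 fixed gene lists (vertical axis) in each cell class (horizontal axis), with an asterisk where camera's adjusted p with a preset correlation was under 0.05 and blank cells where the list was not tested. The mitochondrially encoded list is lowest in excitatory (-0.93) and Wfs1-high (-0.89) neurons. The asterisks of astrocytes above 0 are glucocorticoid response (0.11) and circadian clock (0.12) genes. No list passed in camera with an estimated correlation.

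The genotype effect in excitatory neurons was set against that in astrocytes in 1 model. Without the replicate number as a block, edgeR called 0 of 15921 genes (262 at an unadjusted p under 0.05; DESeq2 0 and 39, limma-voom 0 and 249). With it, 2 genes had a higher and 10 a lower effect in excitatory neurons, 8 of the 12 being mitochondrially encoded, and just 1 was called when nuclei with at least 1% mitochondrial UMIs were left out. Nwd1 had a log2 difference of 0.73 ± 0.13 (adjusted p = 0.000131). Its level was far higher in astrocytes (555 ± 147 CPM in WT and 586 ± 168 in DISC1-N, blocked adjusted p = 0.875) than in excitatory neurons (17.9 ± 3.25 and 31.6 ± 2.63). The difference for mt-Cytb was -0.84 ± 0.12 (edgeR blocked adjusted p = 2.39e-07). In simulated counts for this contrast the blocked fit recovered 16% of 1.5-fold and 42% of 2-fold differences with 4 false calls.

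In DISC1-N oligodendrocytes, Polr3e, a subunit of RNA polymerase III, was higher, at 600 and 443.5 CPM in the replicate 1 and 2 libraries against 304 and 248 in WT. The non-coding RNA 9630013A20Rik, a leading gene of differentiating oligodendrocytes whose model overlaps Pcdh17 on the other strand, stood at 35.5 ± 6.88 CPM (SD, n = 2) in WT and 115.8 ± 1.53 in DISC1-N libraries. Of 10017 genes, edgeR called 0 without a block (23 at an unadjusted p under 0.05; DESeq2 0 and 6, limma-voom 0 and 20) and 6 higher and 1 lower with it. In the blocked fit Polr3e rose by 0.93 ± 0.15 (adjusted p = 3.26e-06) and 9630013A20Rik by 1.70 ± 0.23 (4.99e-10). Polr3e was called under 8 of 10 alternatives and 9630013A20Rik under 7. Nwd1 rose by 1.62 ± 0.38 (0.039, called under 2 of 9; log2 ratios of 2.44 in replicate 1 and 0.46 in replicate 2), the nuclear RNA Neat1 by 0.73 ± 0.16 (0.00588, called under 5 of 10) and the kainate receptor gene Grik1 by 0.88 ± 0.21 (0.0433, called under 0 of 10 alternatives). Nwd1 was far higher in astrocytes, and whether its counts in oligodendrocytes came from other cells was not tested. Vwc2l, a secreted von Willebrand factor C domain protein gene, fell by 1.89 ± 0.38 (0.00125, called under 4 of 8). Myelin genes had 16 of 20 members below 0 (median -0.10, camera adjusted p = 0.0206, 0.306 without the block), with 0 past either threshold and Mal and Cnp among the members of lowest p. Camera at the preset correlation called heat shock (median -0.38; 0 over all genes and 4 adjusted over the list alone), unfolded protein response (-0.22; 0 and 0), oxidative phosphorylation (-0.14; 0 and 0) and ribosomal protein genes (-0.12; 0 and 0) lower. It called glucocorticoid response genes higher (0.13; 0 and 0), though their median log2 ratio was 0.36 in replicate 1 and -0.08 in replicate 2, with adjusted p from 3.18e-07 to 0.0232 for these lists. Short genes as a whole lay lower (blocked median -0.08 in the 1492 shortest and 0.06 in the 1492 longest oligodendrocyte genes of at least 20 CPM). The medians were -0.16 and 0.11 in replicate 2 but -0.03 and -0.05 in replicate 1, so this trend was seen in replicate 2 only. The ribosomal protein list had a median log2 ratio of 0.001 in replicate 1 and -0.279 in replicate 2. Against random lists matched on gene length and level, ribosomal protein genes lay at percentile 66.6, myelin genes at 9.14 and oxidative phosphorylation genes at 2.06. The adjusted p with an estimated correlation was 0.812 to 0.889 for these 6 lists. Lowest in p were Hspa8, Hsp90aa1, Hsp90ab1 and Dnaja1; Hsp90b1, Calr, Pdia3 and Atf4; Ndufb5, Uqcr10, Uqcrfs1 and Ndufa6; Rpl7a, Rps21, Rpl4 and Rpl24; and Nfkbia, Pdk4, Hif3a and Plekhf1. Of simulated changes in oligodendrocytes, 14.1% of genes changed 1.5-fold and 54.4% of those changed 2-fold were recovered with the block, with 4 false calls.

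In oligodendrocyte precursors the blocked fit called Tshz3, a zinc finger transcription factor gene (chromosome 7, 36698118 to 36773553), under 6 of 10 alternatives. Its level was 62.3 ± 10.6 CPM (SD, n = 2) in WT and 137.1 ± 7.27 in DISC1-N libraries, a rise of 1.18 ± 0.16 in the blocked fit (edgeR adjusted p = 0.00756). Of 10737 genes, 0 were called without a block (76 at an unadjusted p under 0.05; DESeq2 0 and 7, limma-voom 0 and 70) and 2 with it, Tshz3 and the Y chromosome model Gm47283. Sapcd2 stood at 29.3 ± 7.16 and 68.2 ± 9.90 CPM (blocked adjusted p = 0.0940) and the model Gm21860 at 36.8 ± 13.3 and 75.4 ± 2.06. Heat shock (median -0.29, 10 of 10 below 0; 0 over all genes and 3 adjusted over the list alone), oxidative phosphorylation (-0.22; 0 and 1), ribosomal protein (-0.22; 0 and 0) and cholesterol synthesis genes (-0.24; 0 and 0) were lower in the blocked fit. Camera gave adjusted p from 8.50e-14 to 0.0206 and an adjusted p of 0.812 for each with an estimated correlation. Lowest in p were Hspa8, Hsp90aa1, Hsp90ab1 and Hspe1; Atp5g3, Cox6a1, Ndufa11 and Cox8a; Rps6, Rplp1, Rpl41 and Rpl8; and the cholesterol enzymes Hmgcs1, Pmvk and Sqle. Precursor and differentiation genes were not called (median 0.00, adjusted p = 0.617). Among simulated changes in precursors, 26.3% of 1.5-fold and 62.8% of 2-fold changes were recovered with the block, with 5 false calls, more than the 2 genes called.

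Microglia of DISC1-N mice had higher levels of 10 genes typical of neurons, while lists of microglial genes were not called. Tenm2, a neuronal adhesion protein gene, stood at 383 and 94.7 CPM in the WT libraries and 917 and 173 in the DISC1-N ones, a rise of 1.17 ± 0.20 in the blocked fit (edgeR adjusted p = 0.000193). The other named rises were the striatal phosphodiesterase Pde10a (1.31 ± 0.31), the GABA-B receptor auxiliary subunit Kctd16 (1.17 ± 0.25) and Ank3, the ankyrin of the axon initial segment (1.05 ± 0.24). Of 7903 genes, edgeR called 0 without a block (28 at an unadjusted p under 0.05; DESeq2 0 and 1, limma-voom 0 and 35; 7 without DISC1-N replicate 2). With the block it called 10 higher and 0 lower (445 at an unadjusted p under 0.05; DESeq2 0, limma-voom 12). None of the 10 was called when nuclei above 3 times the median depth of the class were left out. The median log2 fold change of the 10 was then 0.31, against 0.96 with all nuclei. Excitatory markers in microglia summed to 666 CPM in WT and 842 in DISC1-N replicate 1 but to 347 and 283 in replicate 2. Homeostatic genes (median 0.00, adjusted p = 0.713) and activation genes (9 members, -0.21, 0.0534) were not called. Unfolded protein response (median -0.26; 0 over all genes and 1 adjusted over the list alone), heat shock (-0.36; 0 and 1), oxidative phosphorylation (-0.21; 0 and 0) and ribosomal protein genes (-0.09; 0 and 0) were lower. Camera gave adjusted p from 6.82e-08 to 0.00808 and an adjusted p from 0.812 to 0.889 with an estimated correlation. Ribosomal protein genes of microglia lay at percentile 70.5 of random lists matched on gene length and level. Their median log2 ratio was -0.019 in replicate 1 and -0.285 in replicate 2. Lowest in p were Hspa5, Hsp90b1, Pdia4 and Ern1 (the last with a positive estimate, 0.58 ± 0.35); Hspa8, Hsp90aa1, Hsp90ab1 and Dnaja1; Atp5c1, Ndufc2, Ndufb7 and Uqcrq; and Rpl31, Rpl12, Rpl28 and Rps7. The genes of lowest p without a block were Plekhb2 (55.4 ± 8.23 CPM in WT and 17.9 ± 6.55 in DISC1-N), Tmem259 (15.3 ± 10.3 and 49.1 ± 4.98) and Ipcef1 (34.0 ± 2.91 and 74.7 ± 20.6). In simulated counts for microglia the blocked fit recovered 0% of 1.5-fold and 0% of 2-fold changes, with 0 false calls.

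Endothelial cells numbered 23 and 36 nuclei in the WT and 33 and 49 in the DISC1-N libraries, and called genes included some typical of neighbouring oligodendrocytes or pericytes. Of oligodendrocyte genes, Mbp fell by 2.54 ± 0.58 (blocked edgeR adjusted p = 0.00872), and St18 stood at 100.8 and 97.6 CPM in WT and was listed at 0 in both DISC1-N libraries. Vtn, a pericyte gene, rose by 1.89 ± 0.42 (adjusted p = 0.00525), with Cadps2 (2.08 ± 0.49) and Smc6 (2.60 ± 0.63) also higher. Of 2809 genes, edgeR called 0 without a block (7 at an unadjusted p under 0.05; DESeq2 0 and 3, limma-voom 0 and 46) and 3 higher and 3 lower with it. Without nuclei above 3 times the class median depth none was called (0), and the summed UMIs went from 158664 over 23 nuclei to 17094 over 14 in WT replicate 1 and from 195630 over 33 to 45699 over 23 in DISC1-N replicate 1. Ptgds had 174.0 ± 39.1 and 46.0 ± 7.24 CPM and was not called (blocked adjusted p = 0.122). Ribosomal protein (median -0.46, 0 over all genes and 0 adjusted over the list alone) and glucocorticoid response genes (-0.47; 0 and 1, with Fkbp5 at -1.17 ± 0.42) were lower. Camera gave an adjusted p of 1.76e-07 and 0.0338, and the lists did not pass with an estimated correlation (0.812 for both). Their median log2 ratios were -0.63 and -0.72 in replicate 1 but 0.10 and 0.01 in replicate 2. In simulated counts for endothelial cells, 1.18% of 1.5-fold and 8.89% of 2-fold changes were recovered with the block, with 0 false calls.

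Summed markers of the basolateral amygdala, striatum, central amygdala, and thalamus and habenula were lower in the DISC1-N library of both replicate numbers. Over all nuclei, basolateral amygdala markers summed to 1892 and 1997 CPM in the WT libraries of replicates 1 and 2 and 1770 and 1921 in the DISC1-N ones. Striatal markers summed to 987 and 932 against 857 and 908, central amygdala markers to 825 and 1122 against 728 and 1048, and thalamus and habenula markers to 1051 and 1446 against 969 and 1367. Sums were 554.5 and 669 against 516 and 686 for upper-layer or piriform cortex markers and 927 and 1063 against 925 and 1017 for deep-layer cortex markers. Hippocampal markers summed to 166 and 147 against 175 and 143, and choroid plexus and ependyma markers to 9.34 and 12.4 against 9.13 and 8.88. Blood markers summed to 24.9 and 22.0 CPM in the WT libraries and to 133 in DISC1-N replicate 1 and 22.2 in DISC1-N replicate 2. Y-linked genes were expressed in all 4 libraries, with Eif2s3y at 332.8, 316.5, 295.5 and 294.2 CPM, and Xist was seen in 9 to 17 UMIs per library, so the pools matched in sex.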

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

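Of the tests below, the shuffles of gene order, those among genes of similar length and level, the matched lists for mitochondrially encoded genes, the test of other-cell RNA, both tests without nuclei of high mitochondrial share and the test without deep microglial nuclei were chosen only after the result was seen.

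Lower abundant cytoplasmic, heat shock and mitochondrial transcripts in DISC1-N neurons could come from a trend with gene length and expression level, from less RNA carried over from other cells, or from a few nuclei rich in mitochondrial RNA. Random lists matched on length and level argued against the trend, under the assumption that genes vary independently. In excitatory neurons the 192 nuclear-encoded members of 4 lists had a median log2 fold change of -0.18. The 13 mitochondrially encoded genes had -0.93, and each median lay at percentile 0 of its matched lists. Median log2 ratios of the 192 were -0.088 in replicate 1 and -0.263 in replicate 2, with heat shock alone at percentile 4.14 in replicate 1. Members of a list may vary together, so the random lists cannot tell whether differences among the libraries unrelated to genotype gave the shift. Markers of other classes had a median log2 ratio of -0.09 (the replicate number closer to 0; test value -0.086), which cannot tell, since the interval in replicate 2 reached 0.042. Without nuclei at or above 1% mitochondrial UMIs the log2 ratio of mitochondrial CPM kept 86.8% of its value in replicate 1 (-0.88). This excludes those nuclei as the main cause there. In replicate 2 the ratio kept 28.6% (-0.25 against -0.875 with them). Most of the replicate 2 difference thus went with those nuclei. The value lay between the limits set for the test, which cannot tell whether they were the whole cause. A genotype effect on stress or activity remains possible, and nuclear preparation that differed between pools was not tested.

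Runs of neighbouring genes shifted together over all nuclei on chromosome 2 (175166255 to 177957297, 15 of 15 higher, zinc finger genes and unnamed models) and chromosome X (14 of 15 lower, Bex and Tceal genes among them). Of 1000 shuffles of gene order, 0 gave a window as extreme on chromosome 2 and 0 on chromosome X. Gene order by chance was thus excluded only for genes that vary independently. Neighbouring genes may vary together, so the shuffles cannot tell whether differences among the libraries unrelated to genotype gave the runs. On chromosome 2, 83.3% of gene and class pairs lay above 0, but the run was chosen for its height over the same nuclei, so this cannot tell whether a strain or copy-number variant is carried there, and paralogous gene models make the counts uncertain. Of 1000 shuffles among genes of similar length and level, 0 gave a window as low as that on chromosome X. This argues against a trend with gene length and expression level there, under the same assumption that genes vary independently. No biological explanation was tested for either run.

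Neuronal transcripts higher in DISC1-N microglia could reflect multiplets or neuronal RNA around the nuclei. The median log2 fold change of the 10 genes was 0.96. Without nuclei above 3 times the class median depth it was 0.31 (test value 0.314). Most of the rise thus went with deep nuclei, at a median SE of 0.205 without and 0.196 with them. Leaving them out took DISC1-N replicate 1 from 189 nuclei with 266083 UMIs to 183 with 215670. WT replicate 1 went from 281 to 280 nuclei, WT replicate 2 from 438 to 437, and DISC1-N replicate 2 kept 505. Deep nuclei need not be multiplets, and the value lay between the limits set for the test, which cannot tell. Other neuron-enriched genes had a median log2 ratio of 0.16 in the lower replicate number (test value 0.164), which more free neuronal RNA would give, although excitatory markers summed to 347 CPM in WT and 283 in DISC1-N microglia of replicate 2. A change in the microglia themselves was not tested.

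A difference between the genotype effects of excitatory neurons and astrocytes, tested as an interaction in edgeR with the block, marked 12 genes, and 0 without the block. The log2 differences were -0.84 for mt-Cytb (-0.836), -0.82 for mt-Co3 (-0.821), -0.76 for mt-Co1 (-0.764), -0.78 for mt-Co2 (-0.775), -0.73 for mt-Atp6 (-0.727), 0.73 for Nwd1 (0.726), -0.68 for mt-Nd4 (-0.684), -1.04 for mt-Nd1 (-1.043), -0.93 for mt-Nd2 (-0.931), -0.73 for Fgfr1 (-0.730), -0.60 for Pcdh11x (-0.596) and 0.90 for Il33 (0.903). Among nuclei that the comparisons did not use, 1 unnamed neuron subcluster drew 71 of its 75 nuclei from DISC1-N replicate 1. A single nucleus without a class in DISC1-N replicate 1 held 4678 haemoglobin UMIs, 88.4% of those in the library.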

How the results depend on the processing

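No named gene called in the blocked fit changed sign under that fit's alternatives, while some estimates and differences that passed no test did. Directions of called lists were not compared list by list, and the median of some differed in sign between replicate numbers. Without a block, edgeR called 0 genes in every class under nearly every setting, the exceptions being 17 in excitatory neurons and 1 in Wfs1-high neurons with no expression filter. Leaving out 1 library, with a lone library assumed to vary like the others, gave 0 to 14 calls in excitatory neurons, 1 to 9 in inhibitory neurons, 0 to 7 in microglia, 0 to 9 in Wfs1-high neurons and 14 to 47 called lists. Lists called higher and lower numbered 2 and 32 with all libraries, but 7 and 7 without WT replicate 1, 9 and 7 without DISC1-N replicate 2, and 7 and 40 without either other library. The Disc1 log2 fold change ranged from -0.23 to 0.85 in astrocytes, -0.17 to 0.36 in precursors, -0.66 to 0.15 in microglia and 0.68 to 2.74 in Wfs1-high neurons, and that of Wfs1 in excitatory neurons from -0.65 to -0.07 (-0.069, without WT replicate 1). The replicate block moved the counts to 41 in excitatory neurons, 62 in inhibitory neurons, 17 in astrocytes, 7 in oligodendrocytes, 2 in precursors, 10 in microglia, 6 in endothelial cells, 8 in Wfs1-high neurons and 12 for the interaction, and it changed no other call apart from the lists and named genes given in the report. Leave-one-out fits of the blocked model were not run, since 0 residual degrees of freedom remain. The cause of these changes and those below was not tested.

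With the replicate block, excitatory neurons had 70 calls with DESeq2 size factors, 7 in DESeq2, 219 with no filter, 79 with under 1% mitochondrial UMIs, 109 by own marker score and 16 in thinned sums. Inhibitory neurons had 38, 0, 123, 9, 120 and 12 in the same order, 3 with a doubled doublet share and 24 without deep nuclei. Astrocytes had 0 in DESeq2, 3 with no filter, 6 with at least 1000 genes, 0 with under 1% mitochondrial UMIs, 3 by own score, 0 thinned and 1 without deep nuclei. Oligodendrocytes had 0 in DESeq2, 4 in limma-voom, 0 with at least 1000 genes, 2 with a doubled doublet share, 4 by own score and 17 without deep nuclei. Precursors had 0 with DESeq2 size factors, 0 in DESeq2, 1 in limma-voom, 10 with no filter, 11 with at least 1000 genes, 5 by own score, 6 thinned and 0 without deep nuclei. Microglia had 0 in DESeq2, 5 with no filter, 35 with at least 1000 genes and 0 without deep nuclei. Endothelial cells had 3 with no filter and 0 in DESeq2, with at least 1000 genes, with a doubled doublet share, thinned or without deep nuclei. Wfs1-high neurons had 0 in DESeq2, 5 in limma-voom, 0 with a doubled doublet share, by own score or thinned, 2 without deep nuclei, 13 with a Wfs1 rule of 1.5 times and 45 with subclustering at resolution 1.0. The interaction had 0 in DESeq2, 22 in limma-voom, 1 with under 1% mitochondrial UMIs and 6 thinned.

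Called lists numbered 34 without and 45 with the block, 0 with an estimated correlation or fry, and with the block 0 with an estimated correlation and 1 by fry. The endothelial share differed by 0.125 points with at least 1000 genes and 0.445 with a doubled doublet share, differentiating oligodendrocytes by -0.018 in the latter and mural cells by -0.035 in the former, where both were above 0 in the report. With at least 1000 genes astrocytes also went from -0.900 to 0.076 points and microglia from 0.137 to -0.556. The Wfs1-high share differed by -3.186 points with the 1.5 rule and -1.830 with resolution 1.0. The median of thalamus and habenula markers over all nuclei was -0.13 with the block (-0.130). Of 153 named results of the blocked fit, 130 stayed past the threshold in limma-voom, 125 with DESeq2 size factors and 7 in DESeq2, and of the 143 that thinned sums could test, 40 did; each kept its direction wherever it was tested.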

Other observations

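Among genes of the blocked edgeR fit that the report does not describe, Pycard, the inflammasome adaptor gene, was called higher in both excitatory and inhibitory neurons. The Y chromosome model Gm47283 was called higher in astrocytes, oligodendrocytes, precursors and Wfs1-high neurons. These genes were chosen after their values were seen, and counts of such paralogous models are uncertain.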
